A study of Drosophila melanogaster with 2 samples.

How the data were processed

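Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used, per the labels, to map where a fusion of the nuclear receptor dsf (dissatisfaction) with green fluorescent protein bound the genome of whole Drosophila melanogaster larvae. The fusion protein, dsf-eGFP in the labels, was pulled down with an antibody against the fluorescent tag. The larvae were wandering larvae of the last instar, pooled over males and females, and the chromatin was sheared by sonication, per the labels. The samples formed 1 group of 2 biological replicates, which the labels number 3 and 4 and tie to separate biosamples. The labels name a possible control experiment, which was not analysed here, so no comparison between groups was made.

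The 8 peak files give each region's position, its summit, a signal value and a significance value, on 2 genome builds, dm6 and dm3. Regions are ranked by the signal value deposited by the authors, which is never negative and is used here only to rank, filter or describe regions within a list. The deposited significance column holds the −log10 of a q-value. Each replicate has its own list of peaks and background prepared by the authors as input to the irreproducible discovery rate (IDR) procedure. That procedure is meant to keep regions that replicates rank alike. The series has a list of the same kind without a replicate, and a shorter IDR-thresholded list, which the authors name optimal. The deposited file descriptions state that the series-level list derives from the alignments of both replicates and 1 further file, and it is called the pooled list here. Across 1473 nuclear regions matched in both replicates, its signal value was a median 1.01 times the sum of the replicates' signal values. The shorter list holds exactly the 1731 strongest regions of the pooled list on dm6, and the 1988 strongest on dm3, so its overlap with each replicate's strongest regions is partly built in. The aligner, peak caller, duplicate handling, control normalisation and their versions are not given in the sources used here. The files hold no read counts, so sequencing depth is unknown and no value could be given a depth-based error.

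The main analysis used the IDR-thresholded list on dm6. Chromosome names and region ends fitted the release 6 genome, and genes were taken from the matching annotation (Ensembl release 115), leaving out annotated transposable elements. Coordinates are on dm6 and count from 1. Regions on the arms X, 2L, 2R, 3L, 3R and 4 are called nuclear, and the mitochondrial regions were left out of the tests of features, arms, motifs and gene lists. They count in the shares of regions common to the replicates, and are described in the closing section. The dm3 files were compared only with each other, with no conversion of coordinates.

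Replicates were compared by the share of IDR-thresholded regions with a summit within 100 bp of a summit among the 1731 strongest regions of each replicate, and by correlation of signal values across regions, with intervals from 1000 bootstrap draws of regions. Regions are not independent replicates, so these values describe the lists. A summit within 1 kb of a transcription start site (TSS) was counted as a promoter summit. Promoter and feature shares were compared with 1000 random placements of the summits on the same arms by a two-sided permutation test, whose smallest possible p is 0.001. The feature classes were promoter, 5' UTR, CDS, 3' UTR, non-coding exon, intron and intergenic, in that order of priority. Non-coding exons became a class of their own after the annotation was examined. Arm shares were tested by two-sided exact binomial tests against the share of sequence and of 19252 protein-coding TSS positions. Motifs were counted on either strand within 50 bp of each summit and in flanks of the same total size centred 300 bp away, with a two-sided exact McNemar test. All 2080 hexamers, collapsed with their reverse complements, were scanned in the same way. A gene was called bound when a summit lay within 1 kb of any of its TSS, a label for position only, since no control sample was analysed here, and 30 gene lists were tested with two-sided Fisher's exact tests against the other protein-coding genes. No listed gene was dropped, and 3 symbols were matched to the annotation by hand. Adjusted p-values are Benjamini-Hochberg values over 7 feature classes, 6 arms, 2080 hexamers or 30 lists. Intervals are 95% intervals, exact (Clopper-Pearson) for shares, and cover counting error only. For a list with no bound member, the share allowed is 3 divided by the number of members, an approximate limit in place of the exact one.

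The tests, the gene lists, the named motifs and the rule for naming genes were fixed before the data were examined. The rule names dsf with every region within 5 kb, the protein-coding gene with the TSS nearest each of the 15 strongest regions, the 10 protein-coding genes with the most summits inside the gene or within 2 kb upstream, and up to 4 bound members of each reported list. Mitochondrial regions took 14 of the 15 strongest places of the joint list, mostly through the signal values of replicate 4, so the 15 strongest nuclear regions were named too, a choice made after the values were seen. Ties for the most summits were broken alphabetically. The values of 1 gene that the rule names are not reported here. The alternatives fixed beforehand were other windows, flanks, overlaps and TSS sets, the strongest 25% of regions, the dm3 lists, a stricter list shared by both replicates, each replicate's own strongest 1731 regions in place of the joint list, and random gene lists matched on TSS number or gene length. Alternatives chosen after seeing the data were the count of nuclear regions alone, lower-ranked regions as the comparison for promoter share, dinucleotide-preserving shuffles as the control for motifs, and the comparison of shuffle-enriched hexamers with promoters of unbound genes.

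The procedures were tested on simulated data. With random positions in place of summits, 1 of 20 runs of the promoter test gave a p under 0.05. AAGTCA planted in 3% of 1708 windows at random positions ranked 1 among hexamers (exact McNemar p = 0.000434). Those windows gave 0 called hexamers before planting, unlike the summit windows, so this rank does not carry over to the summits. With bound genes drawn at random, 2 of 100 runs called any of the 30 lists. A planted 4-fold excess in the ribosomal protein list was called in 100% of runs, while a planted 3-fold excess in the nuclear receptor list was called in 31%, so the shorter lists were tested with little power. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.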

Results

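Binding of the dsf-eGFP fusion protein was profiled in 2 biological replicates of whole wandering larvae, numbered 3 and 4. The gene dsf encodes an orphan nuclear receptor of the tailless group, known for its part in sex-specific behaviour and neural development. The IDR-thresholded list held 1731 regions on dm6, with a median width of 404 bp. Of these, 1708 lay on the nuclear arms and 23 on the mitochondrial genome. Each replicate's own list held 29999 ranked regions, background included.

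How well the replicates ranked the same regions was examined as the design's only comparison between samples. The strongest nuclear region, at the promoter of CG14100, ranked 1 among the nuclear regions of replicate 3 and 3 among those of replicate 4 (1 and 19 with mitochondrial regions counted). The region at Ugalt, which encodes a UDP-galactose transporter, ranked 2 and 1 (7 and 17). A region inside ush, with the TSS of the zinc finger transcription factor gene cbt nearest, ranked 4 and 6 (9 and 25). Of the 1731 strongest regions of replicate 3, 973 (56.2%) had a summit within 100 bp of a summit among the 1731 strongest of replicate 4, while randomly placed positions met those of replicate 3 in 0.248% of cases. Those positions were spread over whole arms, while 70.4% of the strongest nuclear summits of replicate 3 and 74.8% of replicate 4 lay at promoters. Any lists rich in promoters would meet more often, so 0.248% is a low floor for this comparison. On average 75.7% ± 2.86 (SD, n = 2) of IDR-thresholded regions had a summit within 100 bp of the 1731 strongest regions of a replicate, 73.7% for replicate 3 and 77.8% for replicate 4. These shares are raised by construction, since the joint list was made from both replicates. Both replicates placed 980 regions (56.6%) of the joint list among their strongest 1731. Anywhere in a replicate's own full list, a summit within 100 bp was found for 1543 of the 1731 regions in replicate 3 and 1668 in replicate 4. Across 1473 nuclear regions found in both lists, signal values correlated with Spearman's rho of 0.562 (95% bootstrap interval 0.522 to 0.600) and Pearson's r of 0.645 on the log10 scale. These are correlations across regions, which are not independent replicates.

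**Figure D1:**
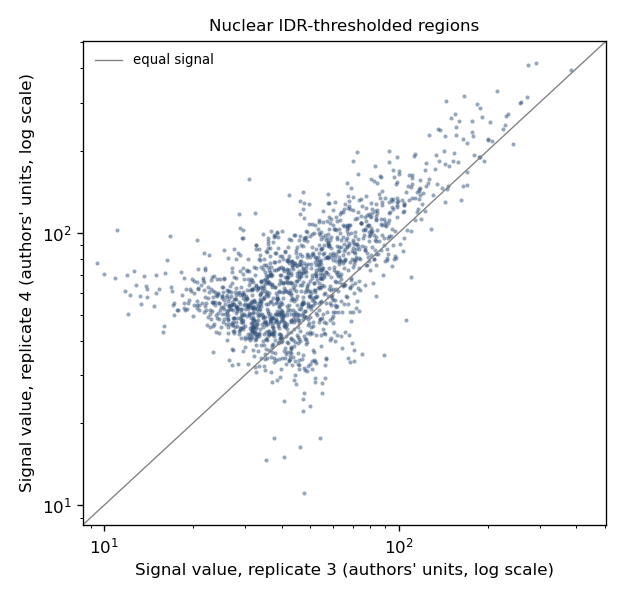
Each point is 1 of 1473 nuclear IDR-thresholded regions matched in both replicates, with the authors' signal value of replicate 3 on the x axis and of replicate 4 on the y axis, both on log scales in the authors' units. Most points lie above the line of equal signal, with a median ratio of replicate 4 to replicate 3 of 1.43.

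The dsf gene itself (FBgn0015381, 2L 5925937 to 5939261, plus strand) held no IDR-thresholded summit. A single region (2L 5943499 to 5943902) lay within 5 kb, with its summit 4440 bp beyond the gene's end. That summit was 58 bp downstream of the nearest protein-coding TSS, which belongs to Gpdh1, the gene of a glycerol-3-phosphate dehydrogenase. The region had a signal value of 192.8 and ranked 204 in the joint list, 161 in replicate 3 and 262 in replicate 4. The pooled list of 29999 regions held 0 summits inside dsf, and the strongest summit inside the gene in replicate 3 ranked only 5314.

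The strongest nuclear regions lay mostly at promoters. Of the 15 strongest, 9 were within 1 kb of a TSS, and signal values ran from 467.9 to 778.9. The strongest lay 108 bp upstream of CG14100 (3L 19590453 to 19590797, signal value 778.9). The region at Ugalt (X 2703737 to 2704059, signal value 712.5) lay 35 bp upstream of its TSS. An intronic region near CG11050 (2L 6612532 to 6612851) had a signal value of 695.2. The region nearest cbt (2L 480952 to 481254, signal value 587.2) lay in an intron. Others among the 15 were promoter regions of CG1888, CG8320, CG18549, Lk6, a kinase of the MNK family, CenG1A, an Arf GTPase activator, Art3, an arginine methyltransferase, and gish, a casein kinase. Regions near CG32772 and CG31668 lay in an intron and in intergenic sequence. The remaining regions had no protein-coding TSS within 5 kb and lay in an intron at 3L 3060661 to 3060932 and in intergenic sequence at 2R 13035218 to 13035463. Of the 15 regions, 14 were among the strongest 1731 of replicate 3 and 15 among those of replicate 4, with the region at CenG1A not matched in replicate 3.

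The 10 protein-coding genes with the most summits held 4 to 8 each. The gene sbb, which encodes a transcriptional corepressor, held 8 summits inside it or within 2 kb upstream. Tlk, a kinase gene, and ush, which encodes a cofactor of GATA factors, held 6 each. The cell adhesion gene kirre, the forkhead gene CHES-1-like and CG1677 held 5 each. Btk, CG43389, the ecdysone receptor gene EcR and the muscle regulator Mef2 held 4 each and are 4 of 17 genes with that number. Most genes with a summit held 1 (1756 genes), while 268 held 2 and 45 held 3. Longer genes offer more room for summits, and these counts were not tested.

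Where binding fell relative to genes was compared with random placement. Promoters held 1243 of 1708 summits, 72.8% (exact 95% interval 70.6 to 74.9), against 23.8% ± 1.05 (SD, 1000 placements), a 3.06-fold excess (permutation p = 0.001, the smallest the placements can give). The lower-ranked regions of the pooled list, a comparison chosen after the data were seen, already had 37.04% of their summits at promoters (odds ratio 4.54, 95% interval 4.07 to 5.08, Fisher's exact test, p = 5.80e-186). No control sample was analysed here, so whether a mock pulldown would show the same promoter regions was not tested, and this applies equally to genes called bound. Of 1184 summits within 1 kb of a protein-coding TSS, 954 (80.6%) lay upstream of it. The median position of all 1184 was -102 bp. Protein-coding sequence was almost empty. Only 7 summits (0.410%) lay in a coding sequence of any gene, against a mean of 291 in the placements. The lower-ranked regions of the pooled list were also well below the placements, with 3.37% in coding sequence against 17.0%. Most of that gap was thus not particular to the IDR-thresholded regions. With promoters given priority, CDS took 1 summit (0.0585% against 10.4%), introns 324 (19.0% against 36.1%), intergenic sequence 124 (7.26% against 25.2%) and 3' UTRs 8 (0.468% against 3.63%), each with a permutation p adjusted over 7 classes of 0.0014. The 5' UTR class (2 summits, adjusted permutation p = 0.0583) and the non-coding exon class (6 summits, adjusted permutation p = 0.517) did not pass the test. Among genes of other kinds, 31 of 269 snoRNA genes (11.5%) and 12 of 290 tRNA genes (4.14%) had a summit within 1 kb of a TSS. So did 151 of 3261 ncRNA genes (4.63%). None of these shares was above the 12.2% of protein-coding genes.

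**Figure D2:**
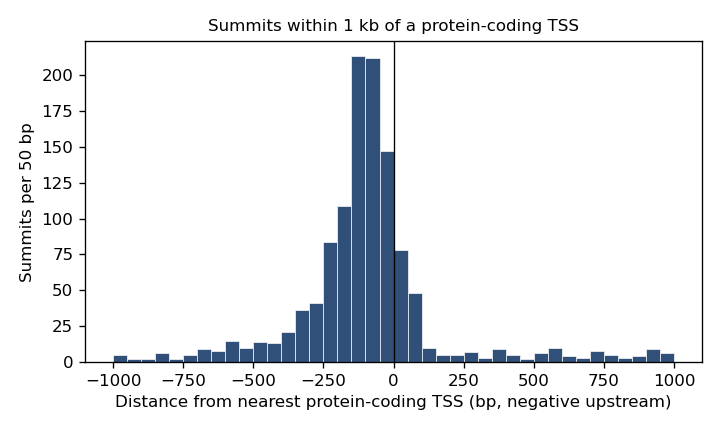
Bars count nuclear summits per 50 bp by distance from the nearest protein-coding TSS, with negative distances upstream. The 1184 summits within 1 kb peak just upstream of the TSS, and 681 of them lie between -200 and -1 bp.

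**Figure D3:**
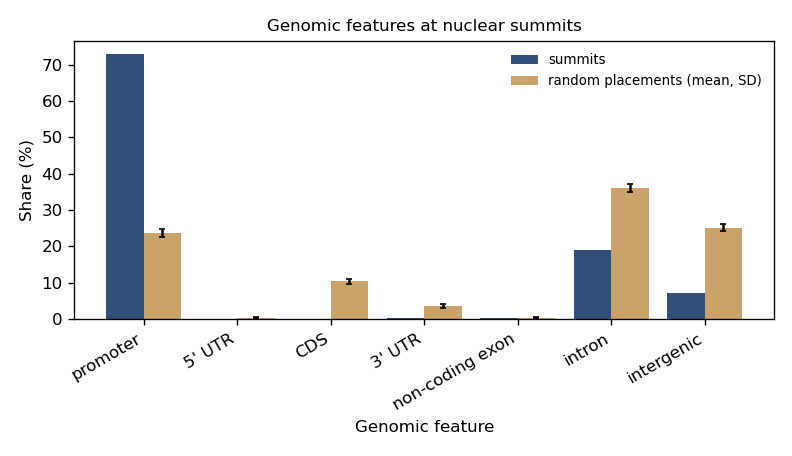
Bars give the percentage of 1708 nuclear summits in each feature class (dark) beside the mean of 1000 random placements (light, error bars SD). Promoters hold 72.8% of summits against 23.8% of placed positions, and CDS, introns and intergenic sequence hold fewer than the placements.

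The X chromosome carried fewer regions than its size or its genes gave. X held 230 regions, 13.5% (exact 95% interval 11.9 to 15.2), against 17.6% of sequence (0.767-fold, adjusted exact binomial p = 3.16e-05) and 17.0% of protein-coding TSS (0.792-fold, adjusted exact binomial p = 0.000439). The call against TSS was lost in the strongest 25% of regions (0.744-fold). X held 9.80 regions per Mb, against 14.1 on 3R and 14.4 on 2L. The small chromosome 4 held 6 regions, 0.353-fold its share of sequence (adjusted exact binomial p = 0.0138) and 0.476-fold its share of TSS (adjusted exact binomial p = 0.0773). Chromosome 3R was above its share of TSS (1.12-fold, adjusted exact binomial p = 0.0157). The 3R call was lost without replicate 4 (1.08-fold), and the call for chromosome 4 against sequence was lost without replicate 4 (0.528-fold). Against TSS, 3L was above (1.11-fold) and 2R below (0.895-fold) their shares, each with an adjusted exact binomial p of 0.0428, and both calls were lost without replicate 3, at 1.101-fold and 0.946-fold. Against sequence, 2L (1.13-fold) and 3R (1.11-fold) were above, each with an adjusted exact binomial p of 0.0236, and both calls were lost without replicate 3, at 1.11-fold and 1.09-fold, as was that for 3R without replicate 4 (1.06-fold).

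The core sequence AAGTCA, which receptors of the tailless group are known to recognise, was not detectably more frequent at summits than beside them. It occurred within 50 bp of 90 of 1708 summits (5.27%) and in the flanks of 71 (4.16%), an odds ratio among discordant regions of 1.28 (95% interval 0.921 to 1.78, exact McNemar p = 0.148). In promoter regions the odds ratio was 1.27 and in other regions 1.30. Among the strongest 25% of regions it was 2.08 (exact McNemar p = 0.0385, with p from 0.0385 to 0.875 over the alternatives).

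A scan of all hexamers found sequences rich in A and T at the summits. Of 2080 hexamers, 344 were more frequent at summits and 716 less frequent (exact McNemar tests, adjusted p under 0.05). TAAATA led, near 568 summits and in the flanks of 233 (odds ratio 3.07, adjusted exact McNemar p = 3.82e-37), followed by AAATAT (598 and 259). All 36 hexamers made only of A and T were among the 344. Of the motifs named in advance, the TATA sequence TATAAA was at 393 summits against 181 flanks (odds ratio 2.62) and TATCGA, the core of the DNA replication-related element, at 173 against 69 (odds ratio 2.73). GAGAGA, bound by the GAGA factor, was rarer at summits (57 against 111, odds ratio 0.495), as was the E-box CAGCTG (58 against 98, odds ratio 0.579). The named word GTCACA is only part of Motif 1, so its result does not cover that motif's other words. No difference passed the test for GTCACA (68 and 52), the E-box CACGTG (19 and 25) or the Zelda site CAGGTA (33 and 35). Nor did one for CGATAA (94 and 84) or AGGTCA (30 and 46). Several of these outcomes depended on the window or the control sequence. The CAGCTG call was lost within 25 bp of summits (odds ratio 0.720, adjusted exact McNemar p = 0.294) and with flanks at 500 bp (odds ratio 0.733, adjusted exact McNemar p = 0.142), where GTCACA passed the test (odds ratio 1.81, adjusted exact McNemar p = 0.00961). Shuffles of each summit window that keep its dinucleotides were a control chosen after the data were seen. TATCGA exceeded the shuffles (173 against 46), and TATAAA showed no excess over them (393 against 397, odds ratio 0.984, adjusted exact McNemar p = 1). GAGAGA did not differ detectably from the shuffles (57 against 41, odds ratio 1.46, adjusted exact McNemar p = 0.410). CAGCTG was more frequent than in the shuffles (58 against 26, odds ratio 2.33, adjusted exact McNemar p = 0.0171), though it was in 98 flanks. This control asks whether a word exceeds what the window's dinucleotides give. The flanks were not shuffled, so it does not show whether a word is commoner at summits than beside them.

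Genes of the cytoplasmic ribosome stood out among the 30 gene lists. Of 81 ribosomal protein genes, 43 (53.1%) had a summit within 1 kb of a TSS, against 11.9% of other protein-coding genes, a 4.46-fold excess (odds ratio 8.36, 95% interval 5.26 to 13.3, Fisher's exact test, adjusted p = 1.39e-17). The strongest were at RpL34b (signal value 208.4, 106 bp upstream), RpL32 (200.2, 132 bp upstream) and RpL7 (194.9, 6 bp downstream). The excess held with either replicate alone, 46 genes without replicate 3 and 31 without replicate 4. It also held against random lists matched on the number of TSS, which had 12.1 bound genes on average (3.55-fold, adjusted permutation p = 0.003, with adjusted p from 8.4e-20 to 0.172 over the alternatives), and was lost in the strongest 25% of regions (2.98-fold). In all, 1695 of 13945 protein-coding genes (12.2%) were bound.

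Regulators of chromatin, cell division and ecdysone signalling were also bound more often than other genes in the main test, with less stable calls. Polycomb and trithorax group genes, which maintain repressed and active chromatin, had 8 of 22 members bound (3.00-fold, Fisher's exact test, adjusted p = 0.0265). They included ph-p (signal value 423.4), brm (199.9), Sfmbt (154.7) and E(z) (126.8). The summit at Sfmbt had no match within 100 bp in replicate 3. Cell cycle and DNA replication genes had 10 of 32 bound (2.58-fold, Fisher's exact test, adjusted p = 0.0265), among them aurA (180.1), stg, the Cdc25 phosphatase gene (111.9), RnrS (107.6) and fzr (107.5). Ecdysone response genes had 9 of 28 bound (2.65-fold, Fisher's exact test, adjusted p = 0.0271), among them Ldh (211.6), Eip63F-1 (142.8), Eip75B (122.6) and the cell death gene hid (112.0). Nuclear receptor genes had 7 of 21 bound (2.75-fold, Fisher's exact test, adjusted p = 0.0480), led by ERR (183.3), Hr96 (180.2), Eip75B and Hnf4 (106.0), and the last list shares Eip75B and other receptors with the ecdysone list. None of these 4 calls held against random lists matched on the number of TSS, where the folds were 2.70, 2.28, 1.57 and 1.75. All 4 held when summits anywhere in the gene or within 2 kb upstream were counted and random lists were matched on gene length, with folds of 2.78, 2.13, 2.22 and 2.22 (adjusted permutation p of 0.003, 0.043, 0.008 and 0.0263). The cell cycle, ecdysone and nuclear receptor calls were lost without replicate 3 (1.49-fold, 1.70-fold and 1.51-fold), and all 4 without replicate 4, where Polycomb and trithorax fell to 1.58-fold while the cell cycle (2.45-fold), ecdysone (2.49-fold) and nuclear receptor (2.49-fold) folds stayed near those of the main test, with adjusted p of 0.0828, 0.0852 and 0.120 by Fisher's exact test.

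Odorant receptor genes, expressed in sensory neurons, had 0 of 54 members bound, which allows a share of up to 5.56%, and were below other genes (Fisher's exact test, adjusted p = 0.0208). Against random lists matched on the number of TSS, 0 were bound where 5.19 were expected, and the call was lost (adjusted permutation p = 0.126). It was also lost in the strongest 25% of regions, with 500 bp windows, over gene bodies (1 bound) and in the stricter list, and kept without either replicate. No member was bound among 28 midgut digestion genes, 34 cuticle genes, 27 neuropeptide genes, 21 testis and spermatid genes, 18 chorion, vitelline membrane and yolk genes, 16 hemocyte genes, 15 accessory gland genes, 12 ecdysteroid synthesis genes, 10 tracheal genes and 8 Hox genes, which allows shares of up to 8.82% for cuticle genes and up to 37.5% for Hox genes, and none of these lists passed the main test. Oxidative phosphorylation genes had 8 of 32 bound (2.06-fold, Fisher's exact test, adjusted p = 0.166), including blw (208.0), Cyt-c-p (189.2), ND-24 (142.7) and COX8 (132.2), and passed the test without replicate 3 with 10 bound (2.49-fold) and over gene bodies against length-matched lists with 9 bound (2.24-fold, adjusted permutation p = 0.0476). Heat shock genes had 4 of 15 bound, Hsp27 (355.2), Hsc70-5 (179.2), Hsp83 (152.7) and Hsp26 (117.6), and passed the test over gene bodies with 6 bound (2.78-fold, adjusted permutation p = 0.0476). Proteasome genes had 4 of 31 bound, Rpn3 (182.0), Rpn5 (178.4), Rpn6 (143.0) and Rpn12 (88.1). The summits at Rpn3, Rpn5 and Rpn12 had no match within 100 bp in replicate 3. Disc patterning genes had 6 of 54 bound, led by sd (95.1), aos (91.0), dac (89.7) and C15 (86.7).

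Lists of sex determination and neural genes, the processes dsf is known for, did not pass the main test. In the sex determination list only gro, a corepressor gene, was bound (1 of 15, 0.548-fold, signal value 183.0). Each replicate's own strongest regions gave 4 of 15 (2.12-fold without replicate 3 and 2.32-fold without replicate 4), and gene bodies gave 5 of 15 (1.83-fold against length-matched lists), none past the test. Neural progenitor factors had 2 of 32 bound, numb (149.3) and brat (123.0), and differentiated neuron genes 2 of 24, elav (171.9) and Syx1A (77.3). The summit at Syx1A had no match within 100 bp in replicate 3. Axon guidance genes had 1 of 26 bound, unc-5 (107.0). Glial genes had 3 of 13 bound (1.90-fold), moody (156.0), Gs2 (84.3) and loco (76.4), and Enhancer of split genes 3 of 11 (2.25-fold), E(spl)m7-HLH (111.8), E(spl)m2-BFM (107.2) and E(spl)mdelta-HLH (99.1). Over gene bodies Enhancer of split passed the test against length-matched lists (4 of 11, 4.22-fold, adjusted permutation p = 0.043). Fat body genes had 3 of 15 bound, Apoltp (133.7), Desat1 (90.0) and bmm (84.1), and clock genes 2 of 11, sgg (149.5) and vri (73.6). The summit at Desat1 was not matched within 100 bp in replicate 3, nor that at bmm in replicate 4. In the muscle list Mef2 (79.0) was the only bound gene of 22, and in the salivary gland list fkh (295.1) the only one of 16. None of these lists passed the main test, and lists this short can miss a real excess.

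**Figure D4:**
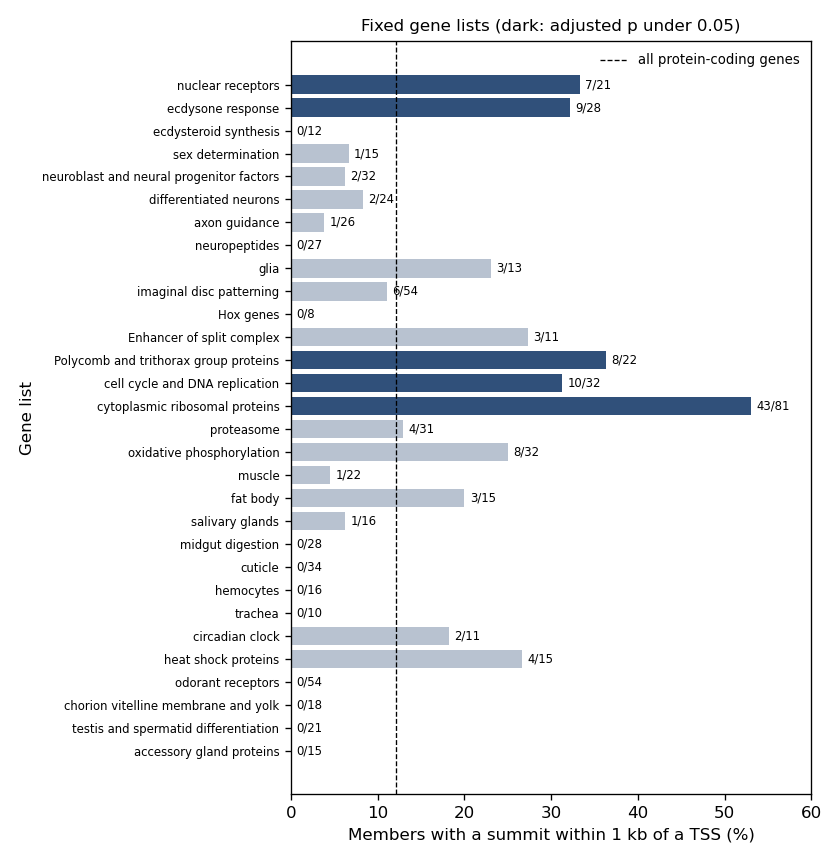
Bars give the percentage of each gene list's members with a summit within 1 kb of a TSS, labelled with bound and total members, and dark bars mark lists with an adjusted p under 0.05 by Fisher's exact test. The dashed line is the 12.2% of all protein-coding genes, cytoplasmic ribosomal proteins reach 53.1%, and odorant receptors, also past the test, have no bar because 0 of 54 were bound.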

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

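The tests on the mitochondrial regions were chosen after the result was seen. On dm6, 23 regions of the IDR-thresholded list lay on the mitochondrial genome, a signal outside the nuclear comparisons, with no control sample analysed here to set it against. They lay in mt:CoI, mt:Cyt-b, mt:ND5 and other genes, and 14 of them had a higher signal value than the strongest nuclear region (up to 2175 against 778.9). Replicate 4 carried this order, with mitochondrial signal values up to 2003 against 419.8 at its strongest nuclear region, while in replicate 3 the highest mitochondrial value (354.2) was below the strongest nuclear one (384.1). On dm3, 1 IDR-thresholded region was mitochondrial and 5 lay on the sequence named Uextra. The strongest region there was nuclear (778.9), and none was wider than 404 bp. Why the builds differ was not tested.

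Separate binding sites of the kind seen on the nuclear arms cannot be told apart from a signal spread along the genome. The regions covered 62.7% of the mitochondrial genome, but 23 separate regions of the usual nuclear width would already cover 47.6% of a genome this short. The mitochondrial entries did not all have that width, since several summits shared wide intervals. The widest ran from 1190 to 4091 (2902 bp, against a median of 404 bp in the list). Whether such intervals hold a spread signal or closely set sites was not tested. A difference in mitochondrial DNA content between the libraries stays open as a candidate explanation. The median ratio of replicate 4 to replicate 3 was 5.66 over 15 matched mitochondrial regions, outside the 0.779 to 2.84 (5th to 95th percentile) of nuclear regions, but single regions ranged from 1.77 to 12.8, partly inside that range, and a difference in content alone would scale them alike. No biological explanation was tested.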

How the results depend on the processing

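The promoter excess kept its direction and its call under all 8 alternatives, from 55.0% to 80.9%, and X stayed under its share of sequence under all 3. The cause of the changes below was not tested, except that stricter lists hold fewer regions. Mean replicate concordance was 79.5% with any overlap, 72.8% with 50% reciprocal overlap, 67.7% within 50 bp, 89.3% with 2 times as many regions, and 95.03% in the strongest 25%. The stricter list held 980 regions. Hexamers enriched numbered 182 in the strongest 25% and 57 against shuffles, an alternative chosen after seeing the data. AAGTCA had an odds ratio of 2.08 in the strongest 25% and 0.963 against shuffles. Called lists numbered 0 in the strongest 25%, 1 with 500 bp windows, 1 against TSS-matched lists, 1 in the stricter list, 8 over gene bodies with length-matched lists (Enhancer of split, oxidative phosphorylation and heat shock added, odorant receptors lost), and 2 to 4 without a replicate.

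In the strongest 25%, folds were 2.98 for ribosomal proteins, 2.85 for nuclear receptors, 1.06 for ecdysone response, 4.08 for Polycomb and trithorax, 0.931 for cell cycle and 0 for odorant receptors, none called. With 500 bp windows they were 2.64, 1.98, 2.94, 2.31 and 0 for the last 5. With TSS-matched lists they were 1.75, 1.57, 2.70, 2.28 and 0, and in the stricter list 2.70, 2.53, 1.93, 1.77 and 0. Odorant receptors had a fold of 0.147 over gene bodies. Without a replicate, folds ran from 1.51 to 2.49 for nuclear receptors, 1.70 to 2.49 for ecdysone response, 1.58 to 3.26 for Polycomb and trithorax, and 1.49 to 2.45 for cell cycle.

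For arms, the strongest 25% lost X against TSS (0.744-fold), 2R (0.856) and 3L (1.13) against TSS, 3R against sequence (1.01) and TSS (1.03), and chromosome 4 against sequence (0). Without a replicate, folds ran from 1.11 to 1.16 for 2L, 0.937 to 1.02 for 2R and 1.06 to 1.09 for 3R against sequence, 0.294 to 0.528 for 4, and against TSS from 0.866 to 0.946 for 2R, 1.101 to 1.13 for 3L and 1.08 to 1.11 for 3R. Non-coding exons took 0.293% to 0.468%.

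Uncalled lists changed direction in these cases. Sex determination had folds of 1.99 in the strongest 25%, 2.12 to 2.32 without a replicate and 1.83 over gene bodies. Differentiated neurons had 1.24 and salivary glands 1.86 in the strongest 25%. Enhancer of split had 0 there and 0.837 with 500 bp windows. Proteasome had 0.841 to 1.80 without a replicate and 0.912 in the stricter list, and fat body 0 in the strongest 25% and 0.943 in the stricter list. Clock genes had 0.721 without replicate 3, 0.837 with 500 bp windows, 0.812 over gene bodies and 0.974 against TSS-matched lists. Of 139 values under alternatives that answer a comparison, 80 were unchanged, 41 kept the direction but lost the call, 1 gained a call, 4 changed direction and 13, which have no test, moved. With single genes and uncalled lists added, 400 of 489 were unchanged, most of which had no call to lose. No paired analysis was possible because there was 1 group. Depth is unknown, so what it limits was not measured.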

Other observations

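The shuffle control, the tests of library preference and of place relative to the TSS, and the comparison of hexamers at bound and unbound promoters, were chosen after the results were seen. Once each summit window was compared with a shuffle of itself that keeps its dinucleotides, the order of the leading hexamers changed in part. CGATAG (123 summits, 17 shuffles), TATCGA (173 and 46) and ATCGAT (148 and 38), overlapping parts of the DNA replication-related element bound by Dref, led, followed by AAATAT (598 and 388) and ACACTG (150 and 46). TAAATA (568 and 413) and AAAATA (663 and 501), made only of A and T, ranked after ACACTG. Such words were thus more frequent at summits than the windows' dinucleotides give, but the flanks were not shuffled for comparison. TATAAA showed no excess over the shuffles (393 and 397). AAGTCA was at 90 summits and in 93 shuffles. At promoter summits CGATAG occurred in 9.97% of 1184 windows, against 4.92% of windows at the same distances from TSS of unbound genes (odds ratio 2.14, 95% interval 1.72 to 2.64) and 0.954% of the other summits. For TATCGA the shares were 12.8%, 8.01% and 4.01%. The unbound windows were drawn with repeats, so these intervals are too narrow.

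The summits were rich in A and T, with 66.8% A and T in 101 bp against 56.3% in the flanks. Place relative to the TSS is argued against as the whole cause, since promoter summits exceeded distance-matched windows at unbound genes by 7.21 percentage points (95% bootstrap interval 6.66 to 7.73). Those windows were not centred on summits and held 59.3% A and T. Lower-ranked promoter summits, not matched on distance, already held 64.6%, so part of that gap was not particular to the IDR-thresholded regions. A preference of the libraries for such fragments cannot be told apart from other causes, because the windows disagree. Within 200 bp of the summit, IDR-thresholded regions held less A and T than lower-ranked regions (a difference of -1.49 percentage points, 95% bootstrap interval -1.72 to -1.22), while within 50 bp they held more (66.8% against 65.0%, a difference of 1.82, interval 1.41 to 2.22). Both signs were the same among promoter regions alone (-0.747 and 1.93) and among the others (-3.10 and 2.34). Recurring sequence words remain open, with 57 of 2080 hexamers enriched and 54 depleted against the shuffles (exact McNemar tests, adjusted p under 0.05), and 9 of the 36 hexamers made only of A and T among those enriched, and sites of promoter factors such as Dref are a candidate source. No biological explanation was tested, as the design has 1 group.

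The X chromosome held fewer regions than its share of TSS. Lower X copy number in mixed-sex larvae cannot be told apart from other causes here. Dividing X signal values by 0.75 raised the X share of regions past the threshold to 21.8% (exact 95% interval 19.96 to 23.7), above the 17.0% of protein-coding TSS, an outcome that neither of the stated predictions covered, and how the signal values were normalised to a control is not given in the sources used here. X also held 15.01% (exact 95% interval 14.3 to 15.7) of 10469 lower-ranked promoter regions, below its share of TSS. Among 1243 IDR-thresholded promoter regions its share was 12.6% (10.8 to 14.5). Fewer promoter regions found on X at lower ranks too thus stays a candidate. It cannot be told apart from lower copy number, since both sets of regions come from the same libraries. No biological explanation was tested.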
